A study of Geotalea uraniireducens Rf4 with 6 samples.

How the data were processed

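The series measured gene expression in Geobacter uraniireducens (Geotalea uraniireducens) strain Rf4, a bacterium that grows by oxidising acetate, with 6 dual-channel CombiMatrix oligonucleotide arrays. Per the labels' protocols, the Cy5 channel carried RNA of cells grown to mid-log phase in batch cultures of Rifle sediment given acetate, and the Cy3 channel carried RNA of cells grown to mid-log phase with acetate as electron donor and fumarate as electron acceptor. Per the labels' protocols, total RNA was polyadenylated and amplified with a kit for bacterial RNA before direct labelling. The submitters' design gives 3 biological replicates, each hybridised in duplicate (arrays A and B). The sources used here do not say whether the replicate cultures were grown at separate times. Every array carried sediment in Cy5 and fumarate in Cy3, so a dye effect on a probe cannot be separated from the difference between the cultures.

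Per the file headers, the deposited scanner files were made with GenePix Pro 6.0.1.26 from scans at 635 and 532 nm and hold the intensity of each spot in each channel, not normalized. The headers name a subtraction of negative controls, but the background columns it fills are 0 in every row, so the spot intensities are taken as uncorrected. The headers also give the local brightness around each spot, which exceeded the spot's own mean Cy5 signal for 73.4 to 90.1% of gene probes depending on the array. The local values were therefore not subtracted in the main analysis, and were used in alternatives. The authors' deposited value table holds log2 ratios for 11705 gene probes. The submitters' processing notes name limma with no step. Its row numbers were matched to array positions from the values, since no file states the match. Set against the scanner files in that way, its values had correlations of 0.92 to 0.97 per array with the loess ratios, with the same direction, sediment over fumarate. Its column medians were 0 on every array except 1B, where the median was 0.02. How its background was treated and why some values are exactly 0 stay unknown. The genome assembly behind the contig numbers in the probe names is not given in the sources used here.

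A complete array had 12544 positions, of which 11795 were gene probes of 35 to 40 bases for 4170 genes. The file of replicate 2, array A, lacked usable values for 412 positions. Of the genes, 3492 had 3 probes, 641 had 2 and 37 had 1. Probe names give a contig, a gene number and the first and last base of the probe within the gene for 4116 genes. The other 54 genes have names that start with gura and carry no contig, and some of them may be the same genes as numbered ones. None of the numbered-gene probes had a stop codon when read in the frame its start position gives, against 42.3% and 36.8% in the other frames, so positions count from 1 at the first base of the coding sequence. The files do not pair probes with gene names. For that reason the functional gene lists fixed beforehand, which are defined by gene symbols and product names, could not be tested.

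All steps used R 4.3.3 and limma 3.58.1. Mean spot intensities were corrected with normexp and an offset of 50, with empty positions and spots marked bad left out, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess (span 0.3) fitted on gene probes. Spots of a probe and the 2 arrays of a biological replicate were averaged, then the probes of a gene were averaged on the log2 scale, which gave 3 values per gene. limma's lmFit and eBayes tested the mean ratio against 0, with Benjamini-Hochberg adjustment over 4170 genes and an adjusted p threshold of 0.05. No filter on dim probes was applied. A probe counted as above background in a channel when its intensity exceeded the median of the 70 negative-control spots by more than 3 robust SDs. A gene counted as above background when any of its probes did. The number of arrays limits the precision.

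The genes to be printed were fixed by a rule. It took the 12 largest mean log2 ratios in each direction among genes past the threshold with the same sign in all 3 biological replicates. Those genes also had to be above background in either channel on each of the 6 arrays. Of them, only the 2 largest in each direction are printed by identifier where no product name is known. For a gene whose dim channel was above background on no array, only a bound is given, and 130_113 and 276_4032 have the same bound beside their ratio because some of their probes were below background: the mean normalized log2 signal of the bright channel was set against, per array, the higher of the lowest signal among probes above background and the dim probe's own. Such bounds are open to dye bias. That of 276_4032 is not firm, because a probe of this gene was below background in its bright channel too on some arrays. A run is a stretch of at least 3 consecutive gene numbers on a contig that were all called in the same direction with at least a 2-fold change, and the number of runs was compared with 10000 permutations of the calls over genes. Lists of genes by a short protein motif in the peptide a probe encodes were tested with limma's camera (preset correlation of 0.01), with camera's estimated correlation and fry beside it, and set against 10000 random lists matched on brightness. The motif lists and the runs of at least 2-fold changes were defined after the files had been read and before any list or run was tested. Control probes were placed on the loess curve of the gene probes, averaged over their 2 or 3 spots, and passed through the same moderated test.

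The fit was tested on simulated arrays with the real layout, in which 200 of 4170 genes were changed: 64 of 67 genes at 1.5-fold, 67 of 67 at 2-fold and 66 of 66 at 4-fold were called in the right direction, and 6 of 3970 unchanged genes were called. The median absolute log2 ratios of the changed genes were 0.82, 1.50 and 2.91, more than the folds put in. The folds had been set on signals with the background still in them, so the simulation does not show whether the sizes of real changes are right. The simulation held no probe-specific dye bias, drew the same spread for every array and changed far fewer genes than were called in the real data. Its shares of genes called therefore do not carry over to the real arrays, where array B of replicate 1 stood apart. Alternatives covered background correction, normalization, filters, technical replicates, probe summaries, the authors' values, moderation, thresholds, scan day and leaving out each biological replicate. Scan dates fell on 2 days, with arrays 1A and 2A on the first and the other 4 arrays on the second.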

Results

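The 6 arrays compared, in 3 biological replicates hybridised in duplicate, the transcripts of Geobacter uraniireducens growing in acetate-amended subsurface sediment with those of the same strain growing in medium with acetate and fumarate. The series' title places the question in the physiological state of this species in uranium-contaminated sediment. Arrays are named by biological replicate and duplicate (1A to 3B). The median intensity of gene probes lay between 278 and 445 in the sediment channel and between 1480 and 3246 in the fumarate channel. Between 23.2 and 30.7% of gene probes were above background in the sediment channel, and between 27.0 and 49.4% in the fumarate channel. All ratios below are log2 of sediment over fumarate after loess, so they measure changes relative to the bulk of the genes, whose median was 0.07.

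The largest measured decreases in sediment were larger than the largest measured increases among genes that met the naming rule. Several of these ratios rest on signals below background and are not exact. Of the genes lower in sediment that met the naming rule, 2 are given here. Their order is not settled, because some signals of each reached the scanner's ceiling or lay below background. Gene 113 of contig 130 (130_113) had a measured log2 ratio of -4.11 ± 0.27 (SD, n = 3; limma adjusted p = 1.04e-06). With signals below background raised to the background limit it was at least 12.5-fold lower than with fumarate. The probe at bases 85 to 119 of the gene, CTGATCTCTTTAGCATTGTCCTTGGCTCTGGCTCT, had a log2 ratio of -4.14 ± 0.33, that at 137 to 171, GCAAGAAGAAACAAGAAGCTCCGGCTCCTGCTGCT, -4.20 ± 0.56, and that at 191 to 225, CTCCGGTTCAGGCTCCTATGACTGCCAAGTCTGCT, -4.00 ± 0.38 (SD, n = 3 each). In the fumarate channel the first probe reached the scanner's ceiling on 2 of 6 arrays and the last on 5. In the sediment channel the middle probe was above background on no array, so its ratio is not exact. The other gene, gura129a, was at least 8.28-fold lower in sediment (limma adjusted p = 1.04e-06). Its sediment signal was not well above background on any array, so only this bound is given. Its probe at bases 366 to 400 was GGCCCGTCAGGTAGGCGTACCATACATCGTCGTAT.

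Among genes higher in sediment, gene 4032 of contig 276 (276_4032) had the largest measured ratio that met the rule. This was 2.47 ± 0.08 (SD, n = 3, limma adjusted p = 1.94e-06). It was 2.12-fold higher than with fumarate when fumarate signals below background were raised to the background limit. Its probe at bases 1691 to 1725, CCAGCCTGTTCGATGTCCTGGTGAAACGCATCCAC, gave 1.88 ± 0.21 and its probe at 2350 to 2384, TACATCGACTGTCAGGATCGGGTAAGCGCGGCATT, gave 3.05 ± 0.05 (SD, n = 3 each). The latter was above background in the fumarate channel on no array and in the sediment channel on only 3 arrays, so its ratio is not exact despite its small SD. Gene 255 of contig 151 (151_255) followed at 2.38 ± 0.39 (SD, n = 3; limma adjusted p = 8.85e-06). Its probes disagreed, so this mean does not settle the size of the gene's change. The order of these genes is not settled. The probe at bases 39 to 73, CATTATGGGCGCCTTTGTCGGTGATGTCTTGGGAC, gave 4.09 ± 0.27 and reached the scanner's ceiling in the sediment channel on 1 array, whereas the overlapping probe at 57 to 91, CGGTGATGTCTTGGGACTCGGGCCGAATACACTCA, gave 0.67 ± 0.51 (SD, n = 3 each) and was above background in the fumarate channel on 1 array. Single control probes reached 2.71, above the mean ratios of both genes but below the larger probe ratio of each. The 12 largest increases under the rule spanned log2 ratios of 2.01 to 2.47, and the 12 largest decreases -3.32 to -4.11. Of these, 2 of the increases were above background in the fumarate channel on no array, and 5 of the decreases were above background in the sediment channel on no array, so their ratios are not exact. A gene counted as above background when any of its probes was. Ratios of some others among these genes therefore rest in part on dim probes and are not exact either.

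Many genes with large decreases lay side by side on the contigs. In 17 runs of at least 3 adjacent genes, which took in 4 of the 12 largest decreases under the naming rule, every gene was called lower in sediment by at least 2-fold. These runs held 99 genes, of which 89 were above background in either channel on each of the 6 arrays. Permuting the calls over genes gave a median of 1 run, with the middle 95% of permutations between 0 and 3 (one-sided permutation p = 1e-04, the smallest that 10000 permutations give). No run of this kind was found among genes higher in sediment, where the longest stretch was 2 genes and permutations gave a median of 0 runs. This count was not stable: it reached 8 with a normexp offset of 0 and 6 with the authors' values, exact zeros left out. The 2 longest runs held 14 genes each, with mean log2 ratios of -2.56 ± 0.45 and -2.64 ± 0.40 (SD of the replicate means, n = 3). Runs of 10 genes had means of -2.02 ± 0.40 and -1.85 ± 0.34, and a run of 9 genes a mean of -2.68 ± 0.35 (SD, n = 3). In the first run of 14 and the first run of 10, the run took in every measured gene of its contig. The other 3 of these runs had measured neighbours within 6 genes. The 7 neighbours of the second run of 14 averaged 0.34, the 12 neighbours of the second run of 10 averaged -0.16, and the 6 neighbours of the run of 9 averaged -0.35. The last 6 ranged from -1.56 to 0.04. Mean log2 ratios of the genes in all 17 runs were -1.62 within the arrays of the first scan day and -2.29 within those of the second, beside -2.03 with both days and -1.10 with normexp after local background. Array 1B, scanned on the second day, gave -3.005, against -1.53 to -2.19 on the other 5 arrays, so the means of the days are not a comparison of days alone. The number of runs was 10 without array 1B and also 10 without replicate 1.

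**Figure D1:**
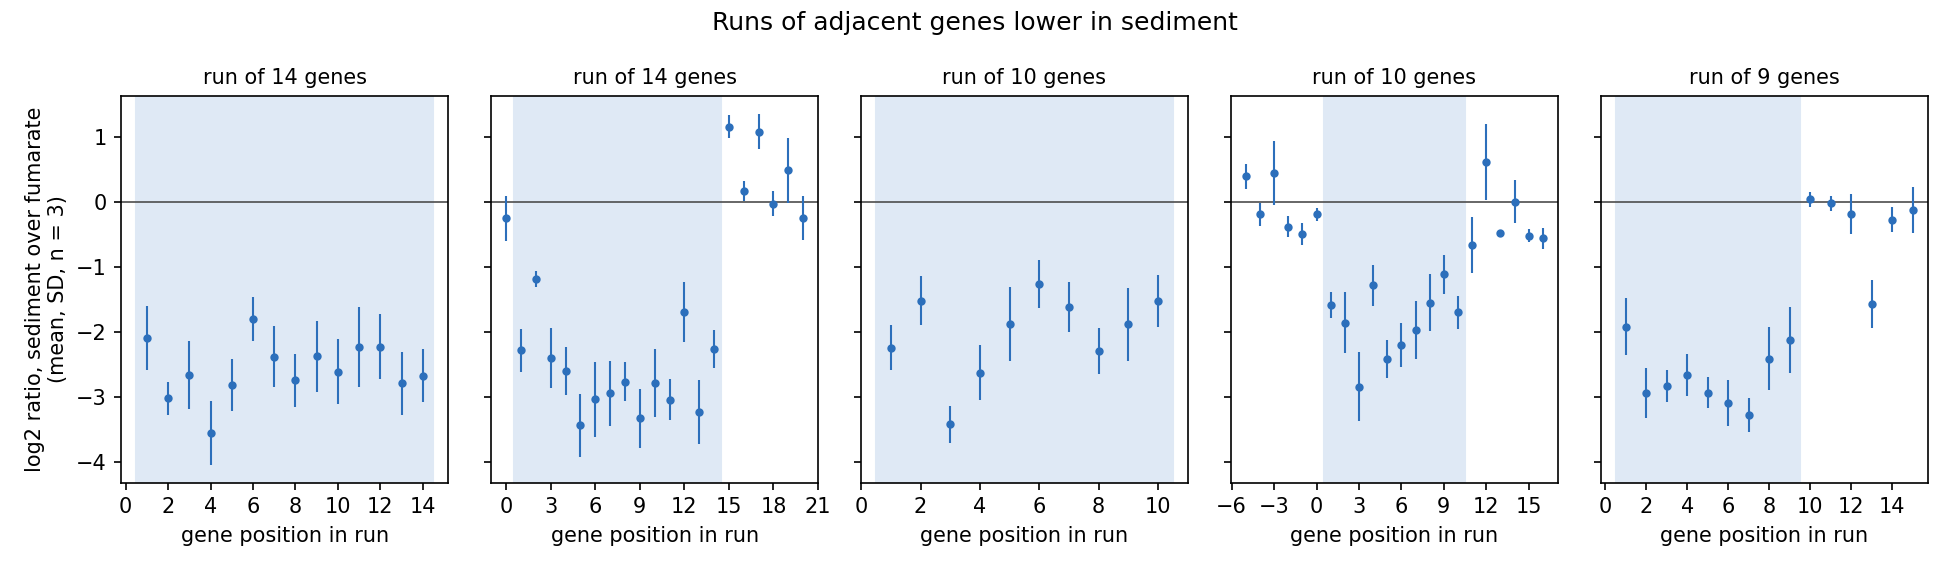
Log2 ratios of sediment over fumarate (vertical axis; points are means and bars SDs over 3 biological replicates) for the 5 longest runs of adjacent genes lower in sediment, by position in the run (horizontal axis), with measured neighbours within 6 genes. Shaded genes belong to the runs of 14, 14, 10, 10 and 9 genes, and the neighbours of the second run of 14 average 0.34.

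Across all pairs of genes with consecutive numbers on a contig (3871 pairs), log2 ratios correlated with r = 0.43. The correlation across gene pairs was 0.27 at a distance of 5 genes, 0.13 at 10, 0.02 at 20 and -0.03 at 50. Genes are not independent replicates, so no p is given. Over the 3762 adjacent pairs with neither gene in a run, r was 0.28. Where both adjacent genes were called, 951 of 1264 pairs had the same direction. The adjacent correlation was 0.31 within the first scan day and 0.48 within the second. It was 0.19 with plain subtraction of local background and 0.21 with normexp after local background.

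**Figure D2:**
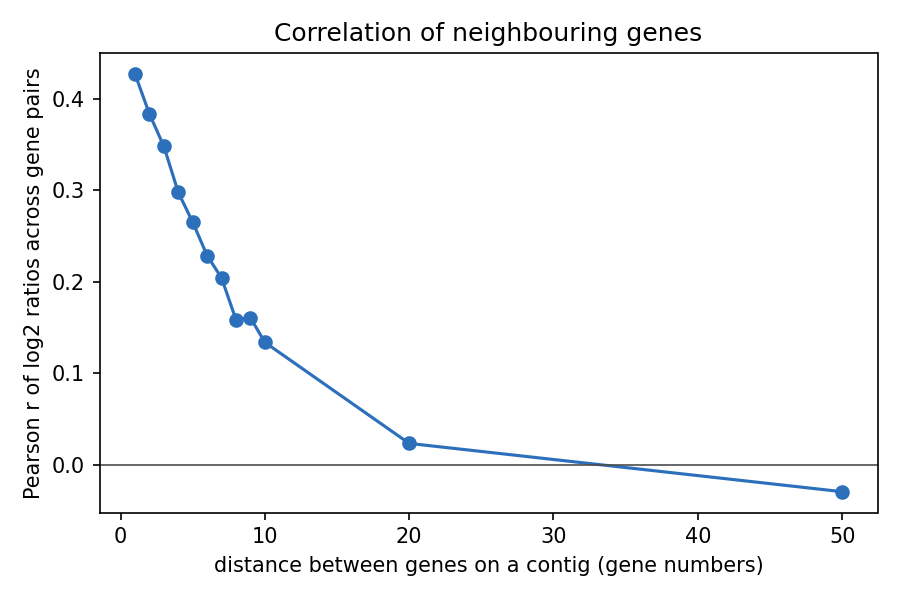
Pearson correlation of log2 ratios across gene pairs (vertical axis) against the distance between the genes in gene numbers on a contig (horizontal axis). Each point is over all pairs at that distance, from r = 0.43 for adjacent genes to -0.03 for genes 50 apart.

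Over all 4170 genes, 2352 were called at an adjusted p under 0.05, 1301 higher and 1051 lower in sediment, and 1818 were not called. Of the called genes, 2344 had the same sign in all 3 biological replicates, which a dye bias constant over the arrays would give too. Of the 2327 called genes with 2 or more probes, 66.2% had all probes of one sign. The median absolute log2 ratio of called genes was 0.62, and 469 genes were called with at least a 2-fold change, 208 higher and 261 lower. That number was 220 without background correction and 769 with a normexp offset of 0. At 4-fold or more, 16 genes were higher and 71 lower, and at 8-fold or more, 1 was higher and 21 lower. This count stands beside a high rate on control probes put through the same test. Of 35 negative-control probes 16 passed the p threshold of the gene probes, as did 7 of 14 probes named for plant genes, together 46.9%, against 49.7% of 11795 single gene probes. At 2-fold or more the shares were 18.4% of control probes and 19.8% of gene probes. Each control probe was a mean of 2 or 3 spots, so these shares are not over strictly like values. Of the called genes, 305 were above background in neither channel on any array. Of the 49 control probes, 4 passed with an increase of 4-fold or more, a larger share than the 16 of 4170 genes. A decrease of that size passed on 0 of them, a rate that so few probes cannot set apart from that of the genes. Control probes spanned -1.68 to 2.71, with 98 called genes below that span and 1 above it. This sets genes, mostly means of several probes, against single probes. The control probes at both ends of the span were above background in the fumarate channel on all 6 arrays, so they may not lack a target here. The extremes of so few probes also do not bound what bias could give among 4170 genes. The count fell to 207 with local background subtracted before normexp, to 960 of 2312 genes with probes above background on all 6 arrays, and to 1282 without replicate 3, which left 2 values per gene.

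**Figure D3:**
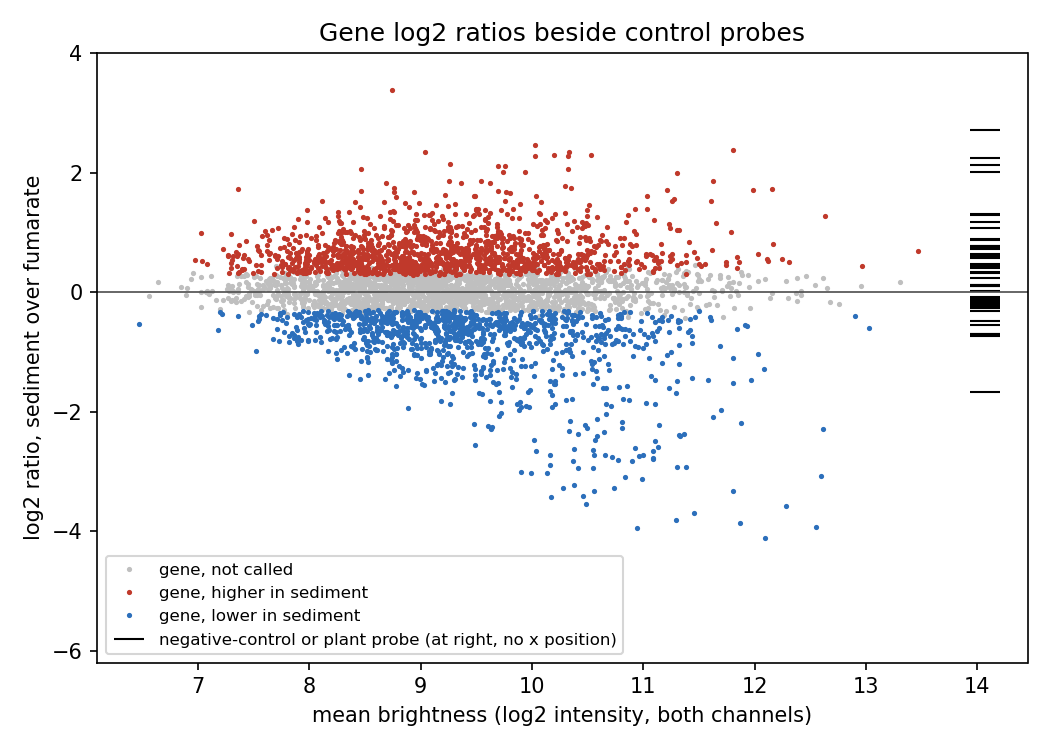
Log2 ratio of sediment over fumarate (vertical axis) against mean brightness of both channels in log2 intensity (horizontal axis) for 4170 genes, coloured by call, with 49 negative-control and plant probes as dashes at the right. Control probes span -1.68 to 2.71, and 98 called genes lie below them. Genes are means over their probes, and controls are single probes averaged over 2 or 3 spots.

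The arrays did not all agree equally well. Across genes, log2 ratios of arrays of the same biological replicate correlated with a mean r of 0.88 (0.75 to 0.95 over 3 pairs), and those of different biological replicates with a mean of 0.86 (0.66 to 0.95 over 12 pairs). Array 1B had correlations of 0.66 to 0.80 with the other arrays, whereas the other 5 arrays had 0.88 to 0.95 among themselves. The consensus correlation of duplicate arrays in limma was 0.06 without scan day in the model and 0.40 with it. Duplicates 1A and 1B, scanned on different days, correlated with r = 0.75, and 2A and 2B, also on different days, with 0.93. The 2 consensus values therefore do not show an effect of scan day apart from that of array 1B. The median SD between biological replicates was 0.19 on the log2 scale. Array 1B left out, 2881 genes were called, of which 2318 were called in the same direction with all 6 arrays.

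By scan day, 2558 genes were called from the 2 arrays of the first day, 1 array for each of replicates 1 and 2. From the 4 arrays of the second day, averaged to 3 biological replicates, 1357 were called. The first day leaves 2 values per gene, which hardly measure a gene's own spread, so these counts cannot be compared with each other. A limma fit to all 6 arrays with scan day as a block and the biological replicate as a random block called 1986 genes, 1083 higher and 903 lower. In that fit, 0 genes differed between the days at an adjusted p under 0.05, and 470 did at an unadjusted p under 0.05.

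By the camera test none of the 4 motif lists shifted, although 1 did with normexp after local background. Of 32 genes with a CxxCH motif, the site at which c-type cytochromes bind heme, in the peptide that a probe encodes, 9 were higher, 8 were lower and 15 were not called, with a median log2 ratio of -0.02 (camera adjusted p = 0.70). Of 9 genes with the CxxCxxC motif of iron-sulfur proteins, 3 were higher, 3 lower and 3 not called (median 0.01, camera adjusted p = 0.79). Of 11 genes with the GxGxxG motif of dinucleotide-binding proteins, 3 were higher and 2 lower (median 0.29, camera adjusted p = 0.70). Of 231 genes whose probe encodes a strongly hydrophobic peptide, 82 were higher, 56 lower and 93 not called (median 0.15, camera adjusted p = 0.70). The median of this list lay above the middle 95% of random lists matched on brightness (-0.04 to 0.13), unlike those of the other 3 lists. With an estimated correlation the adjusted p was 0.92 for each list, and with fry it lay between 0.33 and 0.64. These lists hold only genes in which a probe of about 35 bases happens to cover the motif, so most genes with such motifs are not in them.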

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

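All values here are over the 6 arrays unless stated. An array was picked out when its gap to the nearest other array, relative to the range, exceeded Dixon's 95% critical value. Of 13 measures tested, 6 picked out an array, array 1B each time, where chance gives about 1 in 20. The test on probes with no target in this organism was chosen after the result was seen.

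Array 1B stood apart in its mean correlation with the other arrays (0.74), in its median fumarate-channel signal (3246), in the share of gene probes above background in that channel (49.4%), in the mean correlation of its log2 Cy5 signal (0.93) and of its log2 Cy3 signal (0.86) with the other arrays, and in the log2 ratio of 151_255 (1.53). A fumarate-channel signal unlike the other arrays' is a candidate explanation: its mean Cy3 correlation lay 0.076 below the lowest of the other arrays, past the 0.05 set beforehand, whereas its mean Cy5 correlation lay 0.027 below, within it. A smooth artefact over the slide is argued against, since a surface over rows and columns explained 1.42% of the variance of its deviation, although such surfaces explained 20.3% for array 1A, 29.0% for 3A and 32.1% for 2B. Whether the RNA, its labelling or the hybridisation differed was not tested, and no biological explanation was tested since the duplicate array 1A carried the same replicate.

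The 2352 called genes are the pattern that the control probes put in question. Dye bias set by probe sequence as the whole explanation is argued against: after base composition was removed, non-overlapping probes of the same gene still correlated with r = 0.39 (bootstrap 95% interval 0.36 to 0.43), above the 0.3 set beforehand. A difference in RNA integrity stays open, because the probes nearest the 5' and the 3' end correlated across called genes with r = 0.53, between the bounds of 0.3 and 0.6. A correlation does not register a shift shared by all genes. The median difference in log2 ratio, last probe minus first, was 0.06. Ratios of the kind seen on probes with no target stay open for single genes, since 46.9% of such probes passed. As the whole explanation they are argued against by neighbouring genes. Where both genes were called, 951 of 1264 adjacent pairs had the same direction, against 129 of 256 pairs 50 genes apart. This does not tell how many calls such ratios made. For increases such ratios stay open at large sizes too, with 4 of 49 probes with no target passing at 4-fold or more and the highest at 2.71. That highest probe was above background in both channels on all 6 arrays, so it may not lack a target here. No control probe passed with a 4-fold decrease, but 49 probes are too few to set such decreases apart. Ratios peculiar to single probes would not line up along contigs. The 17 lower runs, against 0 to 3 in the middle 95% of permutations, argue against them for the 99 genes of these runs as a set. That number was 7 with normexp after local background and 0 with plain subtraction. Decreases outside the runs are not covered. Turning the sign of replicate ratios gives 4 ways, too few for a share under 0.05; the real one called 2352 genes and the highest of the others 0. The difference between the cultures that the design names stays among the open explanations, and it shares every array with the dyes.

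Control probes are outside the comparisons of genes. Above background in at least 1 channel on all 6 arrays were 6 of 35 negative-control probes and 1 of 14 plant probes. Whether RNA for the plant probes was added to the samples is not given in the sources used here.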

How the results depend on the processing

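Array 1B left out, single scan days, normexp after local background, empty positions in normexp, the authors' zeros as missing and removed base composition were chosen after seeing the data. Runs and motif lists were added after the files had been read. The 4 genes printed kept direction and call under all alternatives except that 130_113 was no longer called when local background was plainly subtracted (adjusted p = 0.21, -9.41), where the other 3 had no value. The balance of 1301 higher and 1051 lower genes turned to fewer higher than lower with the median of probes (952, 957), with treat, after local background and without within-array normalization. The count of 2352 called genes stayed within 1.5 times under 22 of 31 alternatives. Plain subtraction left 801 genes and limma called 0 (139 at an unadjusted p under 0.05). Normexp after local background called 207 (98 higher, 109 lower). Without within-array normalization, which moved the median of all genes to -1.88, 4136 were called (6 higher, 4130 lower). The filter for probes above background tested 2312 genes and called 960 (534, 426). The B arrays called 1501 (761 higher), treat against 1.5-fold 488 (225, 263), the second scan day 1357 (684, 673), and single probes 5858 (2949, 2909), a count of probes. Fits with a biological replicate left out have 2 values per gene, so their counts are not strictly comparable with the main one. They called 1282 to 2533 genes (682 to 1382 higher, 600 to 1151 lower), lowest without replicate 3. The cause was not tested, except that fewer genes or arrays entered where so stated.

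The 17 lower runs became 9 without background correction, 27 at offset 0, 0 with plain subtraction, 342 without within-array normalization, 10 with the filter, 10 from the A arrays, 10 with array 1B left out, 11 on the first scan day, 7 after local background and 10 to 23 with a biological replicate left out. Higher runs, 0, became 8 at offset 0, 6 with the authors' zeros missing, 3 from the B arrays, 2 with the filter, 2 with median pixel signals, 2 without replicate 2, and 1 each with median centring, the authors' values, replicate 1 or 3 left out and the second scan day. The 469 genes changed at least 2-fold became 220 without background correction, 769 at offset 0, 0 with plain subtraction, 3874 without within-array normalization, 128 after local background and 745 with the authors' zeros missing. Of the 4 motif lists, 1 shifted after local background. The correlation of adjacent genes, 0.43, became 0.19 with plain subtraction, 0.21 after local background and 0.31 on the first scan day. The mean log2 ratio of genes in the runs, -2.03, became -1.65 without background correction, -3.96 without within-array normalization, -1.62 on the first scan day and -1.10 after local background. The median absolute log2 ratio of called genes, 0.62, became 0.45 without background correction, 0.78 at offset 0, 1.89 without within-array normalization, 1.20 with the filter, 0.49 from the A and 0.92 from the B arrays, 0.69 with the median of probes, 0.72 with the authors' values, 0.80 with their zeros missing, 0.77 at an adjusted p under 0.01, 1.31 with treat, 0.50 with array 1B left out, 0.51 and 0.94 on the scan days, 1.10 after local background and 0.58 to 0.87 with a biological replicate left out. The mean correlation of duplicate arrays, 0.88, became 0.52 with plain subtraction and 0.28 after local background. Aquantile leaves ratios unchanged by construction. The planned gene lists were not run, since the files do not pair probes with names. Signal over background limits ratios of dim genes.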

Other observations

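The tests of neighbouring genes and of the heme-binding motif had their bounds set before their results were seen, and the count of runs of any size of change was chosen after the runs of larger changes had been seen.

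Genes named gura formed a small set without contig numbers on the array. Of these 54 genes, 24 were higher in sediment, 11 were lower and 19 were not called, and 4 of the higher and 5 of the lower changed by at least 2-fold. Their median log2 ratio was 0.18, inside the middle 95% of random lists matched on brightness (-0.13 to 0.24). Of them, 10 shared a stretch of at least 20 bases with a probe of a numbered gene, and over the 11 such pairs the correlation was not strong, with r = 0.46. Each of these 10 carries in its name the gene number of a numbered gene that it shares a stretch with. Some genes may therefore be counted under both names, and the pairs may set probes for the same gene against each other. Among numbered genes, 84 shared such a stretch with another numbered gene, and the signals of those genes are uncertain.

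The hypothesis that genes next to each other on a contig moved together, as genes transcribed from a shared promoter would, met both of its bounds: adjacent genes correlated with r = 0.43, above 0.3, and genes 50 apart with -0.03, below 0.1. The first bound was not met with plain subtraction of local background (0.19) or with normexp after it (0.21). Closeness of the probes on the array is argued against as the whole explanation, since probe pairs of adjacent genes at least 20 rows or columns apart still correlated with r = 0.25 (bootstrap 95% interval 0.21 to 0.27), above the 0.2 set beforehand, against 0.25 over all probe pairs. Shared base composition is argued against too, with r = 0.44 after it was removed. Shared transcription was not measured, and the dyes remain tied to the cultures.

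The hypothesis that genes with a CxxCH motif moved as a group was not borne out. The median of the 32 genes lay at percentile 23.1 of random lists matched on brightness, inside the middle 95%, and for 7 genes with the motif read out of frame it lay at percentile 89.2. Across the 31 genes with both kinds of probe, the probe with the motif and the others correlated with r = 0.49. Genes with a strongly hydrophobic peptide lay at percentile 99.3 of matched random lists, with a median of 0.15, but limma's camera test and fry did not call them.

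Runs of at least 5 adjacent called genes of any size of change numbered 31 among genes lower in sediment and 25 among genes higher, where permutations gave medians of 2 and 6 (permutation p = 1e-04 for each, the smallest that 10000 permutations give).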
